A study of Homo sapiens with 8 samples.

How the data were processed

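RNA-seq and ribosome profiling were done in MOLM-13 cells with a control hairpin (shNC) or a hairpin against the peptide's transcript (shSpeptide), with 2 libraries per group and assay. The labels describe the RNA as poly(A) RNA, and footprints as fragments longer than 17 nt after harringtonine and cycloheximide. Group and replicate number came from the sample titles. In the deposited tables the shSpeptide columns carry a different short name from the labels, and they were assigned to shSpeptide because each table holds 2 conditions and the other column is named as the control.

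Per the file headers, the RNA-seq table holds read counts per gene and library, FPKM per library, and the authors' log2 fold change, p-value and FDR. Per the file headers and the values, the Ribo-seq table holds estimated counts and FPKM with 1 column per group, and the authors' own log2 fold change, p-value and FDR. The mean counts step by 0.5 in 83.1% (shNC) and 83.9% (shSpeptide) of nonzero genes, as a mean over 2 libraries does. The deposited log2 fold change of footprints equals the log2 ratio of its FPKM columns, in which 0 was replaced by 0.001. Genes with equal mean counts carry different deposited p-values, in 37 of 37 groups of 10 or more such genes, so the authors' test used more than these means. The submitters' processing notes name Bowtie2, edgeR and hg38, with no versions or roles, and the read counter and annotation are not given in the sources used here. Each table holds 20292 genes, of which 20226 IDs matched the reference names. Coordinates are those of RefSeq genes on GRCh38.p14, joined by current symbol. All per-sample columns were used.

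RNA-seq counts were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over 12068 genes and a threshold of 0.05. The common biological coefficient of variation was 0.13. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 for lists with at least 5 tested genes, and again with an estimated correlation, fry and cameraPR. DESeq2 1.42.0 and limma-voom served as alternatives. In data simulated for the RNA-seq comparison over 11953 genes, 79% of 2-fold and 96% of 4-fold changes were recovered, 6.9% of calls were false, and 0 of 20 unchanged lists were called. The simulated genes were drawn independently and 200 were changed, so it does not show how often camera calls unchanged lists whose genes vary together. Replicates differed by more than sampling noise (chi-square per degree of freedom 29.3 in shNC and 14.0 in shSpeptide) and were kept as 2 libraries.

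The count tests fixed for footprints and translational efficiency need footprint counts per library, and with group means they were not run. In their place the authors' deposited FDR is quoted for footprints. Translational efficiency and the footprint and efficiency changes of lists are described by size with no test, a choice made after the tables were seen. Footprint ratios are ratios of the 2 mean counts with a prior of 0.25, scaled with TMM between the means. Translational efficiency was computed for 10181 genes tested in RNA-seq with a mean of at least 10 footprints and at least 1.5 in each group. Intervals are 95% Clopper-Pearson intervals on the summed counts of each group. They and the floor of 3 counts cover counting error only, and leave out the spread between libraries and the error of the RNA change. List medians are given as percentiles among 10000 random lists matched in 20 bins of expression or of RNA change. In simulated data 3 of 40 unchanged lists lay outside the central 95% and 96% of intervals held the true ratio. These data were also drawn independently for each gene, with counting error alone for the intervals. The depth of single footprint libraries was read from 36 genes with 1 footprint in each group, whose FPKM ratios fall around 0.92 and 3.57. The shSpeptide footprint libraries thus differed about 3.9-fold in depth. The mean counts of shSpeptide therefore come mostly from the deeper library, and so do the footprint and efficiency values computed from them.

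Before the data were examined, 33 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took genes with an adjusted p below 0.05, no overlap between groups and a mean of at least 5 CPM, and of these the 10 largest changes in each direction. It added the 4 members with the smallest p of each list that passed camera, and 15 genes tied to the study's question or to leukemia. For footprints the deposited FDR took the place of the test and the overlap condition was left out. For translational efficiency genes were ranked by size, and lists outside the central 95% of random lists took the place of lists that passed camera. From this set the text names the genes that lead each group. A gene that the rule also named is not reported here. A list of nuclear noncoding RNAs had 0 members in the tables and was not analysed here, nor was the host transcript of the peptide. Lists with fewer than 5 members measured in both assays have no footprint value. Calculations outside R used Python with numpy, pandas, scipy and matplotlib.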

Results

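The series measured messenger RNA and ribosome-protected fragments in MOLM-13 cells, an established human acute myeloid leukemia line of monocytic character. Cells carried either a control short hairpin RNA (shNC) or a hairpin directed at the transcript of a small peptide (shSpeptide). Each of the 4 groups held 2 libraries, which gave 4 RNA-seq and 4 ribosome profiling (Ribo-seq) libraries. Ribo-seq sequences the fragments that ribosomes shield from nuclease, here called footprints. Harringtonine, which holds ribosomes at start codons, was added at 2 µg/ml for 120 s before cycloheximide at 100 µg/ml. The footprints may therefore favour start codons and need not count the ribosomes along each mRNA. The RNA-seq libraries held 20491317 and 20839286 counted reads in shNC and 18541070 and 20200075 in shSpeptide. Footprints were given as 1 mean per group, and these means summed to 4521310 in shNC and 3074946 in shSpeptide. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The test estimates that spread with information shared across genes. The SE and p-value of a gene thus do not rest on its own libraries alone. The targeted transcript was not analysed here, so the hairpin's effect on it gives no check of the labels. ASH1L, followed for the study's question, had an RNA-seq log2 fold change of 0.54 (SE 0.20, n = 2 and 2), with an adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment of 0.0153, and of 0.0545 to 0.216, at log2 fold changes of 0.45 to 0.64, when any 1 library was left out. Leaving out a library leaves 1 in its group, so the spread then comes from the other group alone and the lone library is assumed to vary like it.

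The first comparison asked how the RNA of the cells differed between the hairpins. In shSpeptide 26 of 29 measured genes of the monocyte and macrophage list were higher, while 42 of 42 genes of DNA replication, 33 of 34 of mitosis, 24 of 29 of cholesterol synthesis and SREBP targets and 31 of 37 of ribosome biogenesis were lower. Each of these lists passed limma's camera test with a preset correlation, and each had an adjusted p = 0.191 with an estimated correlation. With an estimated correlation the test has few degrees of freedom at 2 libraries per group, so not passing it does not speak against a list. Of 12068 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5715 passed an adjusted p of 0.05, with 2933 higher and 2782 lower in shSpeptide. At least 2-fold changes made up 1396 of the higher and 913 of the lower genes. The balance depended on the processing, with 2980 higher and 2209 lower with library totals and 2451 and 2502 with DESeq2. The 2 groups did not overlap in 72.8% of genes, where chance gives 33.3%. Without shNC replicate 2 the number of passing genes was 3459. An FDR below 0.05 was given to 4793 genes in the authors' deposited table, 2326 higher and 2467 lower. Of these 4793 genes, 4698 also passed here, 4692 in the same direction.

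Monocyte and macrophage genes were among the largest increases. CD14, a co-receptor for bacterial lipopolysaccharide (ENSG00000170458, chromosome 5, 140631732 to 140633701 in GRCh38.p14), rose 10.1-fold from 9.93 ± 0.19 to 100.2 ± 16.4 CPM (read counts scaled to library size; SD, n = 2). Its log2 fold change was 3.33 (SE 0.19). FCN1, a secreted lectin of monocytes, rose 15.4-fold, and S100A8, a calcium-binding protein of myeloid cells, rose 6.88-fold. Of the 29 measured members of the monocyte and macrophage list, 26 rose and 0 fell, with 26 and 0 adjusted over the list alone and a median log2 fold change of 1.90. The list differed from other genes in limma's camera test (adjusted p = 3.78e-20), and had an adjusted p = 0.191 with an estimated correlation. The surface proteins ADAM28, LILRB3 and LRP1 rose 19.8-fold, 17.3-fold and 13.9-fold. LILRB3 and LILRA6 (14.8-fold) belong to a family of near-identical receptors whose reads the counting can split. SGSH, a lysosomal sulfatase, rose 18.3-fold and SLC26A11, an anion transporter, 32.3-fold. The genes lie beside each other on chromosome 17 (80200673 to 80220333 and 80220427 to 80253500) and do not overlap in these coordinates. Whether reads of one gene were counted for the other was not tested.

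**Figure D1:**
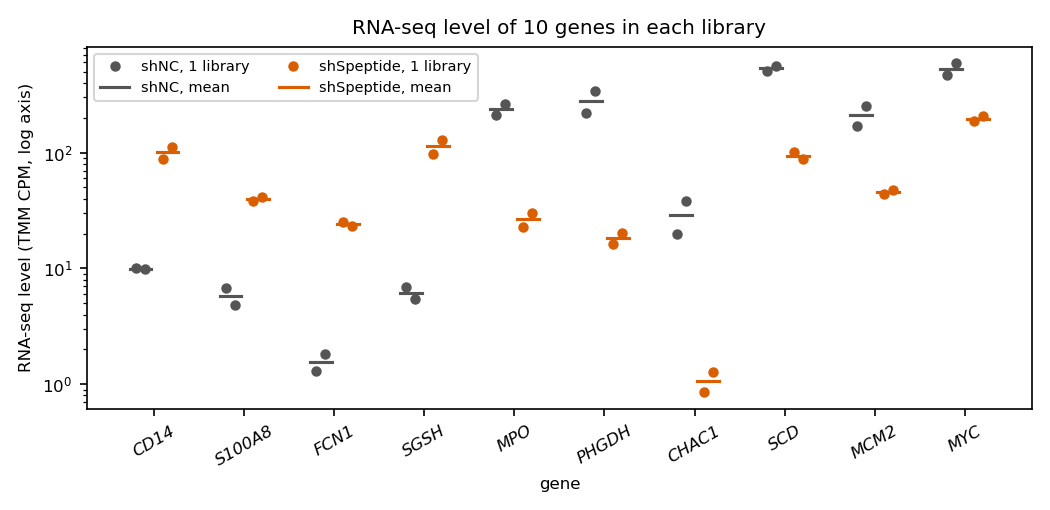
RNA-seq level of 10 genes in each library, as TMM-scaled CPM on a log axis, with a point per library and a bar at the mean of each group of 2. CD14, S100A8, FCN1 and SGSH lie higher in both shSpeptide libraries, and the other genes lie lower, with PHGDH at 279 CPM in shNC and 18.2 CPM in shSpeptide.

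Genes of the promyelocyte granule moved the other way. MPO, the myeloperoxidase of the azurophil granule, fell from 237 ± 38.7 to 26.6 ± 5.30 CPM (8.92-fold lower), and CTSG, a granule protease, was 5.66-fold lower. PRTN3, a further granule protease and one of the most abundant transcripts, fell from 11357 ± 113 to 3877 ± 623 CPM. Of 18 measured members of the granule list, 10 fell and 3 rose (11 and 3 adjusted over the list alone), with a median log2 fold change of -0.67, a camera adjusted p = 9.79e-05 and an adjusted p = 0.414 with an estimated correlation. Inflammatory genes rose in 11 of 19 cases and fell in 2 (11 and 3 adjusted over the list alone), led by IL1B, a cytokine, at 12.9-fold and TNFAIP2 at 4.06-fold (camera adjusted p = 9.79e-05, adjusted p = 0.191 with an estimated correlation). Immediate early genes rose in 16 of 23 cases and fell in 2 (the same counts adjusted over the list alone), with DUSP1, a MAP kinase phosphatase, at 3.59-fold and FOSB, an AP-1 subunit, at 3.62-fold (camera adjusted p = 2.90e-08, adjusted p = 0.191 with an estimated correlation). Targets of p53 rose in 14 of 30 cases and fell in 4 (14 and 4 adjusted over the list alone), among them TP53INP1 at 4.45-fold and MDM2, the ubiquitin ligase of p53, at 2.34-fold (camera adjusted p = 0.0126, adjusted p = 0.265 with an estimated correlation).

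Nearly all measured genes of the cell-division lists fell. All 42 measured genes of DNA replication and the G1/S transition fell, with a median log2 fold change of -1.62. CDT1, which loads the replicative helicase, was 4.75-fold lower, and MCM2, a helicase subunit, went from 211 ± 57.3 to 45.6 ± 2.35 CPM. Of 34 mitotic genes 33 fell and 0 rose, with counts of 42 and 33 adjusted over the list alone. Among the mitotic genes were AURKB, a mitotic kinase, 5.05-fold and TPX2, a spindle factor, 4.47-fold lower. The camera adjusted p was 5.45e-37 for replication and 3.68e-30 for mitosis, and each had an adjusted p = 0.191 with an estimated correlation. MYC, the growth-promoting transcription factor, fell 2.69-fold from 530 ± 82.4 to 197 ± 13.6 CPM.

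Members of the ATF4 and integrated stress response list were among the largest decreases. CHAC1, which degrades glutathione and is induced by the integrated stress response, was 27.1-fold lower and PHGDH, the first enzyme of serine synthesis, 15.3-fold lower (log2 fold change -3.94, SE 0.19; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.27e-89). PSAT1, the next serine enzyme, was 10.1-fold lower, CBS and CTH, which turn homocysteine into cysteine, were 11.9-fold and 12.7-fold lower, and ALDH1L2, a mitochondrial folate enzyme, was 9.71-fold lower. Without shNC replicate 2 the log2 fold changes of PSAT1 and CTH went from -3.34 and -3.67 to -2.68 and -3.05. In the ATF4 and integrated stress response list 22 of 33 genes fell and 5 rose (22 and 5 adjusted over the list alone), with a median log2 fold change of -1.15, and -0.67 without shNC replicate 2 (camera adjusted p = 1.01e-12, adjusted p = 0.319 with an estimated correlation). ATF4 itself had a log2 fold change of -0.47 (SE 0.18), with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.0227, and of 0.0686 without shNC replicate 1, 0.325 without shNC replicate 2 and 0.137 without shSpeptide replicate 1, at log2 fold changes of -0.58, -0.36 and -0.40. Aminoacyl-tRNA synthetases, which charge tRNAs, fell in 15 of 20 cases and rose in 0 (15 and 0 adjusted over the list alone), with AARS 3.32-fold and GARS 2.95-fold lower (camera adjusted p = 2.27e-06, adjusted p = 0.265 with an estimated correlation). In cholesterol synthesis and SREBP targets 24 of 29 genes fell and 0 rose, and 25 and 0 adjusted over the list alone. FADS2 and SCD, which desaturate fatty acids, were 6.60-fold and 5.70-fold lower, and the sterol reductase DHCR7 was 3.16-fold lower (camera adjusted p = 9.87e-15, adjusted p = 0.191 with an estimated correlation).

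Ribosome biogenesis fell in 31 of 37 cases and rose in 0 (31 and 0 adjusted over the list alone), with NOLC1 and FBL, both nucleolar proteins, 2.29-fold and 2.20-fold lower (camera adjusted p = 2.61e-08, adjusted p = 0.191 with an estimated correlation). Mitochondrial ribosomal proteins fell in 50 of 75 cases and rose in 1 (52 and 1 adjusted over the list alone; camera adjusted p = 7.48e-07, adjusted p = 0.342 with an estimated correlation). The 50 became 27, 28 and 29 without shNC replicate 1, shNC replicate 2 and shSpeptide replicate 1. Of 79 cytosolic ribosomal protein genes 13 fell and 0 rose, at a median log2 fold change of -0.24, and -0.15 without shSpeptide replicate 1 (11 and 0 adjusted over the list alone; camera adjusted p = 0.0105, adjusted p = 0.747 with an estimated correlation). The 13 became 5, 0 and 2 without shNC replicate 1, shNC replicate 2 and shSpeptide replicate 1. Elongation and termination factors fell in 6 of 15 cases and rose in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.0435, and 0.066 with 3 lower genes without shNC replicate 2; adjusted p = 0.319 with an estimated correlation). Of the protein-folding and protein-breakdown lists, 18 of 38 ER chaperone genes, 21 of 31 proteasome genes and 13 of 22 heat shock genes fell and 0 rose in each (18, 23 and 13 fell adjusted over the list alone; camera adjusted p = 5.60e-05, 3.30e-04 and 3.84e-04; adjusted p = 0.191, 0.289 and 0.191 with an estimated correlation). The 21 proteasome genes became 13, 6 and 11 without shNC replicate 1, shNC replicate 2 and shSpeptide replicate 1. XBP1, a transcription factor of the unfolded protein response, was 3.29-fold lower. Nuclear-encoded respiratory chain genes fell in 21 of 72 cases and rose in 2 (19 and 2 adjusted over the list alone; camera adjusted p = 0.0207, adjusted p = 0.657 with an estimated correlation), and in 10, 8 and 8 without shNC replicate 1, shNC replicate 2 and shSpeptide replicate 1. Of the 16 replication-dependent histone genes 8 rose and 1 fell (10 and 1 adjusted over the list alone), with HIST1H2AC at 2.76-fold and HIST1H1C at 3.14-fold (camera adjusted p = 0.00435, adjusted p = 0.289 with an estimated correlation). Histone genes are near-identical copies, so reads of single members are uncertain. Poly(A) RNA leaves out most histone mRNA, so these values may report only a polyadenylated minority.

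The camera test called 19 of 32 lists, 5 higher and 14 lower, and 0 with an estimated correlation, where 7 lists had an unadjusted p below 0.05. With 2 libraries per group the estimated correlation left few degrees of freedom. For cholesterol synthesis and SREBP targets it was -0.0092, below the preset 0.01, yet the unadjusted camera p went from 1.23e-15 to 0.0120. The loss of that call thus need not come from genes varying together. Other lists, such as cytosolic ribosomal proteins at 0.477, had a higher estimate. The tests fry and cameraPR called 16 and 20 lists. Of lists that camera did not call, fry called other initiation factors (fry adjusted p = 0.0112). Of the same lists, cameraPR called interferon response (cameraPR adjusted p = 0.0403). The lists that did not pass camera at the preset correlation held the eIF4F complex with poly(A)-binding proteins (2 of 22 genes higher and 5 lower, camera adjusted p = 0.573), other initiation factors (3 and 14 of 32, 0.0844), other mRNAs with a 5' terminal oligopyrimidine tract (1 and 3 of 17, 0.430), mRNAs reported as eIF4E-sensitive (6 and 12 of 25, 0.261), AML drivers (2 and 9 of 28, 0.127), interferon response (14 and 4 of 27, 0.0522), the BCL2 family (4 and 4 of 14, 0.843), glycolysis and hypoxia (10 and 7 of 30, 0.563) and mitochondrially encoded mRNAs (0 and 0 of 13, 0.870). Adjusted over the list alone, the counts were 2 and 4, 3 and 16, 1 and 3, 6 and 12, 2 and 7, 14 and 5, 4 and 4, 10 and 7, and 0 and 0, in that order. Interferon response did not pass camera at the preset correlation with all libraries, at a median log2 fold change of 0.65. When single libraries were left out, which changed the genes tested, its median ranged from 0.59 to 0.97. Over the genes of the fit with all libraries it ranged from 0.55 to 0.77. Under the same omissions, each with its own tested genes, the median of other initiation factors ranged from -0.30 to -0.25, against -0.27 with all libraries. That of AML drivers ranged from -0.29 to -0.07, against -0.15. The genes lower went from 14 to 4 for other initiation factors without shNC replicate 2, and from 9 to 4 for AML drivers without either shNC library or shSpeptide replicate 1. Without shNC replicate 2 they went from 5 to 1 for the eIF4F complex, from 3 to 1 for other mRNAs with a 5' terminal oligopyrimidine tract and from 7 to 2 for glycolysis and hypoxia, and without shSpeptide replicate 1 from 4 to 1 for interferon response. Lists of lymphoid, erythroid and adherent cell markers gave 0.387, 0.884 and 0.860, and the 5 genes followed for the study's question gave 0.577. Of the 18, 20 and 16 listed markers only the 5, 6 and 5 that passed the count filter were tested. They have reads in these cells and are no control made of absent markers. These 4 lists had 1, 3, 1 and 1 members higher and 2, 2, 1 and 2 lower, with the same counts adjusted over the list alone. The BCL2 family had a median of -0.14 and a mean of 0.06, with the test higher, the erythroid list a median of 0.75 and a mean of 0.61, with the test lower, and the adherent list a median of 0.08 and a mean of -0.07, with the test higher. When single libraries were left out, which changed the genes tested, the BCL2 median ranged from -0.10 to 0.04. The erythroid median then ranged from -0.78 to 1.14 and the adherent mean from 0.13 to 1.24. PABPC1, which binds poly(A) tails, was measured at 2462 ± 469 and 2643 ± 65.1 CPM (log2 fold change 0.10, SE 0.20). EIF4G1, the scaffold of the cap-binding complex, fell 1.71-fold, from 487 ± 68.1 to 284 ± 18.1 CPM. Its edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 6.50e-05, and 0.0532 at a log2 fold change of -0.63, against -0.78, without shNC replicate 2. EIF4E had a log2 fold change of -0.45 (SE 0.19) and EIF4A1 one of -0.24 (SE 0.19), and EIF4E no longer passed when any 1 library was left out (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p from 0.0382 to between 0.0579 and 0.276), at log2 fold changes of -0.54 to -0.35. Of the survival and leukemia genes, BCL2 was 4.43-fold and FLT3 2.27-fold lower, MCL1 was 2.02-fold higher, and CDK6 had a log2 fold change of -0.45 (SE 0.16). CDK6 did not pass edgeR's quasi-likelihood test without shNC replicate 1, shNC replicate 2 or shSpeptide replicate 2 (Benjamini-Hochberg adjusted p 0.282, 0.0583 and 0.301), at log2 fold changes of -0.32, -0.57 and -0.25. MYB, HOXA9 and MEIS1 did not pass the test, at log2 fold changes of -0.10, -0.30 and -0.18 (SE 0.17, 0.16 and 0.18). The value of PABPC1 was -0.09 and that of MEIS1 0.00 without shNC replicate 1, and that of MYB was 0.03 without shNC replicate 2.

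The second comparison asked which mRNAs carried more or fewer footprints. An FDR below 0.05 was given to 390 of 14100 genes in the authors' deposited table, 307 higher and 83 lower in shSpeptide. Over 10181 genes with enough footprints the median log2 fold change was 0.242 in the authors' deposited table, and the median log2 count ratio after TMM scaling 0.01. By these count ratios, with no test, 844 of them were at least 2-fold higher and 446 lower. That table gives 1 footprint value per group, so no replicate error of a footprint level can be printed, and the fold sizes below are ratios of the mean counts after TMM scaling. In shSpeptide these means come mostly from the deeper of 2 libraries that differed about 3.9-fold in depth. Of 23 monocyte genes 8 were higher at that FDR in the authors' deposited table and 0 were lower, with log2 ratios of 2.59 for S100A9 (95% counting interval 2.34 to 2.84), 2.46 for VCAN and 2.38 for CD14 (FDR 8.76e-08, 2.54e-08 and 9.35e-05 in the authors' deposited table). FCN1, with a log2 ratio of 3.42, had an FDR of 0.0668 in the authors' deposited table. ADAM28 went from a mean of 8 to 171.5 footprints and ADAMDEC1 from 34.5 to 420.5. Of 30 genes of the ATF4 list 8 were lower at that FDR in the authors' deposited table and 3 were higher. The lower ones had log2 ratios of -3.19 for ASNS, which makes asparagine, -2.76 (-2.95 to -2.59) for PHGDH and -2.28 for PSAT1, among others (FDR 6.84e-12, 2.16e-10 and 6.80e-07 in the authors' deposited table). CHAC1 and CBS, at log2 ratios of -3.13 and -1.29, had an FDR of 0.212 and 0.614 in the authors' deposited table. Among 29 sterol and SREBP genes 13 were lower at that FDR in the authors' deposited table and 0 were higher. Their examples were FADS2, SCD, HMGCS1 and INSIG1 at log2 ratios of -2.85, -2.30, -2.27 and -1.94. MPO had a log2 ratio of -1.92, MYC one of -1.14 and BCL2 one of -1.58, each below an FDR of 0.05 in the authors' deposited table.

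Several of the largest deposited footprint changes were those of genes that share sequence with others. HSPA1A, a heat shock protein with a near-identical copy, had a mean of 0 counts in shNC and 227 in shSpeptide, at least 208-fold higher against a floor of 3 counts over the group. GOLGA8J, CT45A1 and the read-through gene RPS10-NUDT3 were at least 54.3-fold, 33.7-fold and 55.2-fold higher, and the read-through gene CHURC1-FNTB at least 26.5-fold lower, on the same floor. CORO7-PAM16, CBWD6 and HIST2H2AA4 likewise have copies or parent genes, so these values are uncertain.

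The footprint medians of 16 of 29 lists lay outside the central 95% of random lists of similar expression, 4 above and 12 below. Above lay monocyte genes (median log2 ratio 0.96, 20 of 23 genes above 0), p53 targets (0.72, 23 of 29), immediate early genes (0.49, 19 of 21) and mitochondrially encoded mRNAs (0.27, 9 of 12). Below lay sterol genes (-1.20), the ATF4 list (-0.97), mitosis (-0.88), histones (-0.85), aminoacyl-tRNA synthetases (-0.77), granule genes (-0.77), replication (-0.70), cytosolic ribosomal proteins (-0.48), ribosome biogenesis (-0.45), other initiation factors (-0.32), eIF4E-sensitive mRNAs (-0.31) and mitochondrial ribosomal proteins (-0.29). With the deposited FPKM ratio the medians were 1.09 for mitochondrially encoded mRNAs, 1.27 for p53 targets, 0.86 for immediate early genes and -0.56 for the ATF4 list. That ratio was not centred, and its median over all genes with enough footprints was 0.242. This compares 1 mean per group and is a description, not a test.

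Of the 373 deposited footprint calls that were also tested in RNA-seq, 331 passed in the same direction, 9 in the opposite direction and 33 did not pass. Genes higher in both numbered 268 where independent lists would share 71.3, and genes lower in both 63 where they would share 17.8, among 11821 genes. Over 10181 genes with enough footprints the log2 changes of footprints and RNA correlated across genes at a Pearson r of 0.61 and a Spearman rho of 0.591. Genes are not independent replicates, so no p-value is given. With 1 RNA-seq library per group the r ranged from 0.543 to 0.618. Of 1632 genes that changed at least 2-fold in RNA and passed the test, 90.4% had a footprint change in the same direction. In 84.9% footprints changed less than RNA in the direction of the RNA change, and these include the genes that went the other way. Picking genes by a large RNA change favours such a result.

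**Figure D2:**
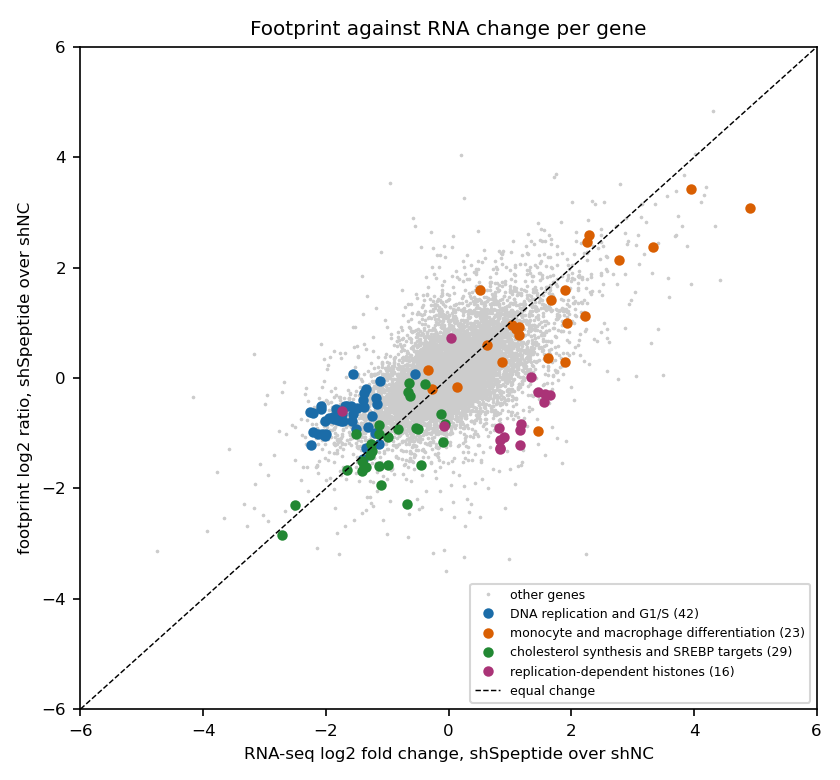
Footprint log2 ratio against RNA-seq log2 fold change for 10181 genes, shSpeptide over shNC, with 4 gene lists in colour and a dashed line at equal change. Of the 42 replication genes 40 lie above the line, most of them on the left, and 14 of the 16 histone genes lie below it. The RNA is poly(A) RNA, which leaves out most histone mRNA.

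The third comparison asked whether footprints changed more or less than RNA, which is the change in translational efficiency. It is the footprint log2 ratio less the RNA-seq log2 fold change and is described here by size, with no test, because footprints were given as group means. Intervals cover the counting error of the footprints only. Harringtonine was added, so footprints may favour start codons, and the measure need not reflect ribosomes along the whole mRNA. Translational efficiency was at least 2-fold higher for 605 genes and lower for 479, so that 55.8% of these were higher. With library totals in place of TMM for the footprints the split was 773 and 390 (66.5% higher), and with the deposited FPKM ratio, centred on its median, 1143 and 696 (62.2% higher). Without that centring it was 1802 and 412 (81.4% higher). List medians given below with deposited FPKM are not centred, and over these genes the deposited log2 fold change had a median of 0.242. Their percentiles are set against random lists that carry the same offset. Medians of lists are set against 10000 random lists of equal size and similar expression. Of 29 lists, 14 lay outside the central 95% of their random lists, 6 above and 8 below. By chance 1.5 would, if the genes within each list were independent. Genes of a list can vary together, so more can lie outside by chance. Because this measure contains the RNA change with its sign turned, lists were also compared with random lists of similar RNA change, and 6 of the 14 then stayed outside on the same side.

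Histones stood furthest apart. Over 16 measured members the RNA median was 1.03 and the footprint median -0.85, so that translational efficiency had a median log2 change of -1.96 (0.00th percentile on both comparisons; random lists -0.138 to 0.322). Poly(A) RNA leaves out most histone mRNA, so for histones this measure may not set footprints against the mRNA that was translated. HIST1H2BK had a change of -2.12 (95% interval -2.20 to -2.05) and HIST2H2BE one of -2.10 (-2.19 to -2.01). Cytosolic ribosomal proteins had a median of -0.19 over 79 genes, of which 56 lay below 0 (0.00th percentile on both comparisons), with RPL36A at -1.10, RPS24 at -0.86 and RPL24 at -0.72. Interferon genes had a median of -0.59 (0.02nd percentile, and 0.36th among lists of similar RNA change), with IFIT2 at -2.51 (-3.48 to -1.70) and MX1 at -2.49 (-3.90 to -1.54), on RNA levels in shNC of 0.32 and 1.07 CPM. Sterol and SREBP genes had a median of -0.12 with counts and 0.01 with deposited FPKM, and lay at the 1.74th percentile, the 0.00th among lists of similar RNA change, and the 3.22nd, inside the central range, with deposited FPKM. Among them were HMGCS1 at -1.59 and MSMO1, a sterol oxidase, at -1.13.

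Replication genes had a median translational efficiency change of 1.04 (100th percentile, and 99.48th among lists of similar RNA change), with 40 of 42 above 0. MCM10 stood at 1.65 (1.41 to 1.89), MCM2 at 1.57 (1.46 to 1.69) and TYMS, which makes thymidylate, at 1.57 (1.47 to 1.68). The BCL2 family had a median of 0.51 (99.55th percentile, 99.75th among lists of similar RNA change, and 91.37th, inside the central range, with deposited FPKM), led by BBC3, a p53-induced killer protein, at 1.55 (1.22 to 1.88). For the other lists outside the first comparison, the median lay inside the central range among lists of similar RNA change. These were mitosis (median 0.96, 89.4th percentile of similar RNA change), ribosome biogenesis (0.32, 34.65th, and 38.92nd of similar expression with deposited FPKM), ATF4 and integrated stress response (0.34, 18.24th), ER chaperones (0.26, 50.08th), monocyte genes (-0.30, 74.6th), inflammatory genes (-0.45, 4.35th), immediate early genes (-0.33 with counts and 0.35 with deposited FPKM, 33.75th, and 77.7th of similar expression with deposited FPKM) and glycolysis (-0.14, 3.12th). When single RNA-seq libraries were left out the median ranged from -0.30 to -0.07 for ribosomal proteins, from -0.61 to -0.35 for interferon genes, from -0.23 to -0.07 for sterol genes, from 0.06 to 0.64 for the ATF4 list, from -0.41 to -0.20 for monocyte genes and from -0.29 to -0.06 for glycolysis. The other 15 lists lay inside the first comparison. Of these, 5 lay outside among lists of similar RNA change: p53 targets (median 0.22, 99.63rd percentile), other initiation factors (-0.04, 1.03rd), eIF4E-sensitive mRNAs (-0.11, 1.74th), aminoacyl-tRNA synthetases (0.06, 0.44th) and respiratory chain genes (0.02, 0.93rd). Their medians ranged from 0.11 to 0.30, -0.14 to 0.04, -0.24 to -0.02, -0.04 to 0.17 and -0.03 to 0.12, in that order, when single RNA-seq libraries were left out. With the deposited FPKM ratio, not centred on its median of 0.242, the medians were 0.61 for the ATF4 list, 0.44 for ER chaperones and -0.19 for monocyte genes. They were -0.07 for inflammatory genes, -0.32 for glycolysis, 0.60 for p53 targets and 0.19 for eIF4E-sensitive mRNAs. The eIF4E-sensitive list then lay at the 35.47th percentile of similar expression.

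**Figure D3:**
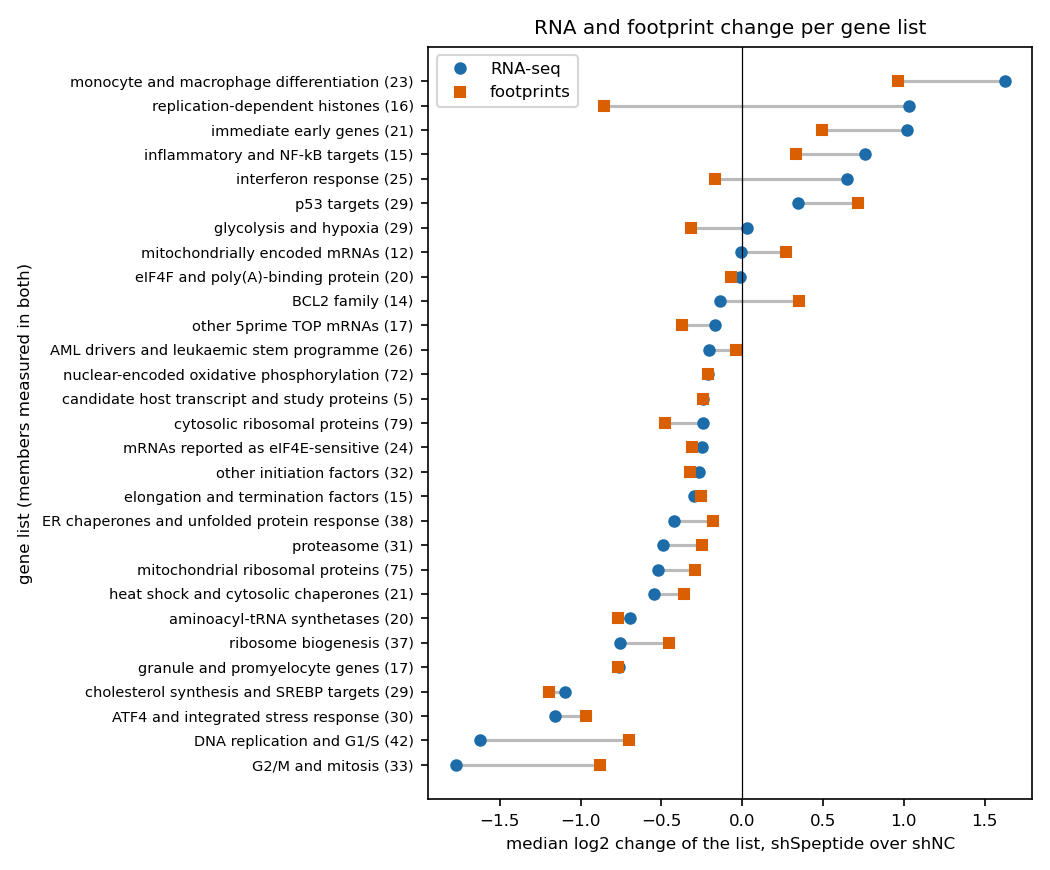
Median log2 change of RNA (circles) and footprints (squares) for 29 gene lists, shSpeptide over shNC, with the number of members measured in both assays. Histones lie at 1.03 in RNA and -0.85 in footprints, and replication genes at -1.62 in RNA and -0.70 in footprints. The RNA is poly(A) RNA, which leaves out most histone mRNA.

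Among single genes with a mean of at least 5 CPM in both assays, translational efficiency was lowest for HIST2H2AA4 at -4.25, XAGE1A at -3.49, TLR9, a sensor of bacterial DNA, at -3.39 and VPS33B at -3.04. It was highest for INO80B at 3.83 (2.82 to 5.28), on 3.49 mean footprints in shNC, and then TMEM189-UBE2V1 at 3.25, CBWD6 at 2.94 and TCF19 at 2.69. XAGE1A, TMEM189-UBE2V1 and CBWD6 share sequence with other genes. For HIST2H2AA4, a histone gene, the limit of poly(A) RNA given above applies. MT-ATP8, which overlaps MT-ATP6 on the mitochondrial genome, stood at 2.42 (2.38 to 2.46). Of the genes tied to the study's question, PABPC1 had a change of -0.41 (-0.46 to -0.36), EIF4G1 0.20 (0.12 to 0.27), EIF4E 0.20 (0.01 to 0.39), EIF4A1 0.39 (0.36 to 0.42), MYC 0.29 (0.22 to 0.36), MCL1 -0.78 (-0.93 to -0.63) and ATF4 0.67 (0.57 to 0.78). The eIF4F list (median 0.06, 36.11th percentile) and the eIF4E-sensitive list (4.40th percentile) lay inside their random lists of similar expression. The eIF4F median ranged from 0.009 to 0.124 when single RNA-seq libraries were left out.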

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

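Alternatives for translational efficiency and for the lists of footprints, the filters on the deposited FDR, and the deposited FPKM ratio were chosen after seeing the data. The number of RNA-seq genes past the threshold stayed within 1.5 times of 5715 under the other normalizations, tests, filters and FPKM, at 4646 to 5705. Requiring a 2-fold change as well gave 2309, by construction. Leaving out 1 RNA-seq library gave 3459 to 4229, with fewer samples. With the replicate number as a replicate block 6656 genes passed, 5713 of them among the 5715. The numbers are not stated to mark a shared culture, and same-numbered deviations correlated at 0.322 over 2 pairs. For lists, the replicate block left 19 calls with camera and 0 with fry, an estimated correlation gave 0 in place of 19, fry gave 16, and leaving out 1 library gave 19 to 22 with camera. With fry these omissions gave 5 lists without shNC replicate 1 and 0 without each other library (smallest adjusted p 0.0776, 0.0944 and 0.0591). Each omission and the replicate block also leave fewer degrees of freedom than the main fit. How far this lowers the number of fry calls was not tested. Over the 4 omissions of 1 library the log2 fold change ranged from -0.09 to 0.31 for PABPC1, from -0.35 to 0.00 for MEIS1 and from -0.22 to 0.03 for MYB, and turned in sign or reached 0 with changes that did not pass the test. Of the 102 genes followed in RNA-seq, 11 lost their call in at least 1 alternative.

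The count of genes with a 2-fold change in translational efficiency, 1084, went to 471 with at least 50 footprints and 654 at 5 CPM or more, where fewer genes were counted. It went to 1839 with the deposited FPKM ratio centred on its median and 2214 without centring, where the median lay at 0.242; the cause was not tested for the count. Leaving out 1 RNA-seq library gave 1044 to 1318. The correlation of 0.61 went to 0.677 with at least 50 reads and 0.54 with deposited FPKM, and leaving out 1 RNA-seq library gave 0.571 to 0.614; the cause was not tested. Of 88 named genes, 48 had a deposited footprint log2 fold change outside the counting interval of the count ratio. Of 14 lists outside their random lists in efficiency, 10 stayed so on the same side with deposited FPKM, which also put 4 further lists outside: other mRNAs with a 5' terminal oligopyrimidine tract (0.58th percentile), mitochondrially encoded mRNAs (100th, median 0.85 against 0.16), respiratory chain genes (0.09th) and the proteasome (0.52nd). With counts, the efficiency median of mitochondrially encoded mRNAs ranged from -0.155 to 0.401 when single RNA-seq libraries were left out. The planned edgeR, DESeq2 and limma fits of footprints and of the interaction, their blocks, and the omission of footprint libraries were not run, since footprints are group means. No paired analysis was possible for footprints because the columns carry no replicate number.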

Other observations

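KEGG pathways as annotated in the deposited tables were tested after the data were seen, with camera over RNA-seq. Of 304 pathways 82 passed, 41 higher and 41 lower, and 0 with an estimated correlation, where 13 had an unadjusted p below 0.05. Here too the estimated correlation left few degrees of freedom. The tests fry and cameraPR called 98 and 83. Lysosome genes were higher in 50 of 113 cases and lower in 12 (camera adjusted p = 0.00246, adjusted p = 0.685 with an estimated correlation). Osteoclast differentiation, a pathway of the macrophage lineage, was higher in 53 of 107 cases and lower in 8 (camera adjusted p = 1.29e-06, adjusted p = 0.590 with an estimated correlation). Spliceosome genes were lower in 70 of 130 cases and higher in 8 (camera adjusted p = 1.65e-04, adjusted p = 0.590 with an estimated correlation), and mismatch repair genes in 18 of 22 and 1 (camera adjusted p = 1.29e-06, adjusted p = 0.590 with an estimated correlation).

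For the patterns below, the tests of summed histone counts, of unequal library depth and of lists matched on RNA count were chosen after the result was seen. Footprint changes were smaller than RNA changes across genes, with a slope of 0.546. Sampling error of the RNA change would flatten the slope, but with the other pair of libraries as instrument it was 0.591 (bootstrap SD 0.015), below the 0.8 that was set as the bound. Few footprints or a constant background per gene would spare well-covered genes, but in the 2546 genes with the most footprints the slope was 0.586 (SD 0.016), against 0.512 in an equal share with the fewest. A difference in translation between the hairpins, which the design names, stays open and was not tested.

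Histone RNA was higher while histone footprints were lower. Reads split among the 16 measured genes would cancel in a sum, but their summed counts still had an efficiency change of -1.79. The list fixed 29 genes, and reads split with copies outside the 16 do not enter the sum, so that part stays open. Poly(A) selection, which leaves out most histone mRNA because it lacks a poly(A) tail, is a candidate explanation. In shNC the median log2 ratio of footprint to RNA CPM was 7.73, where the central 95% of lists matched on footprints ended at 1.67, so the RNA libraries may report only a polyadenylated minority. A difference in histone translation between the hairpins stays open, and was not tested.

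The deposited footprint fold change was also set against the ratio of mean counts before TMM scaling. The difference had a median of 0.62 log2 units and ranged from -0.67 to 3.02 among 6785 genes with at least 50 footprints per group. The totals alone give 0.56. Unequal depth of the shSpeptide libraries could raise single genes by at most 1.83, and 42 genes lay above that bound with a tolerance of 0.3, 3 of them deposited calls, so depth does not account for these 42. Gene lengths that vary with the isoforms may contribute. The spread of FPKM per count over the RNA-seq libraries was 1.99 times that of other genes in the 37 of them with enough RNA reads (permutation p = 0.0028), and lay at the 99.32nd percentile among lists matched on RNA count. The lengths themselves were not analysed here.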
